A study of Homo sapiens with 11 samples.

How the data were processed

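RNA sequencing counts of 11 libraries of human neural cells were used. Per the labels' protocols, human embryonic stem cells were turned into neural stem cells by inhibition of both SMAD branches, and the cells at d20 were then grown to d40 along 1 of 2 routes. The 4 libraries of the group PFC come from cells given FGF8 at 50 ng/ml and SHH at 25 ng/ml and are labelled prefrontal. The 4 libraries of the group OCC come from cells maintained without a listed addition of these factors and are labelled occipital. The 3 libraries of the group NSC are neural stem cells of the d20 stage that the submitters took from another series. Their titles differ, with UMOD_d20 for NSC 1, R6_UMOD for NSC 2 and R6_MEL1 for NSC 3, and these codes were not used to divide the group. RNA was extracted with Trizol and sequencing libraries were made with a standard Illumina preparation, per the labels' protocols.

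The labels give the embryonic stem cell line H9 and total RNA for the d40 libraries, and the embryonic stem cell line MEL1 and polyadenylated RNA for the NSC libraries. Stage, labelled line, RNA selection and series of origin therefore change together in every comparison with NSC. The deposited sample sheet gives line numbers 1 to 4 that the same-numbered OCC and PFC libraries share, although the labels name the line H9 for all 8, and for the 3 NSC libraries its line numbers differ from those in the titles. In a check of transcripts known to differ between the lines named in the labels, 8 of the 11 libraries did not match the line they are labelled with. The groups are named here as the labels name them, and the line of the libraries labelled H9 is left open. No label says that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. No pair of libraries held identical values.

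Per the submitters' processing notes, CASAVA 1.4, STAR, HTSeq and DESeq2 were used with the genome build hg38; the versions of the last 3, the gene annotation and the strand setting are not given in the sources used here. The deposited table holds whole-number read counts per gene, not normalized by the authors, for 58051 Ensembl genes, of which 56948 carried a symbol and 57447 were found in GENCODE release 29 (GRCh38, the same build as hg38). Coordinates printed here are from that release. A total of 13026 genes had 0 counts in all libraries, and 0 lines named no gene. Library totals ran from 23611599 to 40773916 counts, so that 3 counts in a library correspond to between 0.074 and 0.127 CPM (counts scaled to a common library total). Reads of genes with processed pseudogenes (ribosomal proteins, KRT8, LDHA) or with copies (7SL RNA) could be divided by the authors' counting. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart; genes named only as antisense transcripts were not reported.

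Changes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (limma 3.58.1, DESeq2 1.42.0), on the deposited counts with TMM factors, after the filterByExpr filter by group, 2-sided, and with Benjamini-Hochberg adjustment at 0.05. Each of the 3 comparisons used only the libraries of its 2 groups and no covariate. Fold changes are those of the first group over the second, and the standard error (SE) is the fold change divided by the root of the F statistic. Levels are given as CPM with TMM factors over all 11 libraries, as mean ± SD. For a gene with 0 counts in a whole group a lower bound of the fold was computed against 3 counts over the group. For 1 to 3 counts the ratio was given with an exact 95% interval that covers counting error only. Fitted fold changes of such genes depend on the prior count.

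The 35 gene lists were fixed in advance. They cover pathway responses (FGF, hedgehog, WNT, BMP, retinoic acid, Notch), cortical regions (rostral patterning centre and frontal cortex, caudal and occipital cortex, cortical hem and choroid plexus, ventral telencephalon and interneurons) and other regions (hypothalamus, thalamus and other diencephalon, retina and pigment epithelium, midbrain and hindbrain, HOX genes). Others cover cell types outside the brain (neural crest and mesenchyme, surface ectoderm and epithelium, pluripotent cells, endoderm and mesoderm) and neural cell types (radial glia and neural stem cells, astrocytes and oligodendrocyte lineage, intermediate progenitors, pan-neuronal, deep-layer and upper-layer cortical neurons). The last cover functions (cell division, glutamate and GABA receptors, synapse and axon adhesion, autism-associated genes from exome studies, hypoxia and glycolysis, the unfolded protein response) and technical classes (mitochondrially encoded mRNAs, replication-dependent histones, non-polyadenylated small RNAs, cytosolic ribosomal proteins). Some genes are in more than 1 list. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists. Members past the gene test were counted with the adjustment over all tested genes and adjusted over the list alone. Counts are given out of the members that passed the filter. Between PFC and OCC these were 6 of 14 listed genes for retina, 6 of 14 for surface ectoderm, 6 of 13 for pluripotent cells and 7 of 15 for hypothalamus. Such counts say nothing of the untested members. Because the preset correlation is small, camera with an estimated correlation and fry were run beside it.

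The rule for named genes took, among genes past the threshold with a mean of at least 1 log2 CPM and no overlap between the groups, the 12 largest rises and 12 largest falls for PFC against OCC and 6 of each for the comparisons with NSC. It also took up to 4 members per list, and NKX2-1, PAX6, SOX2, NR2F1, SP8, GLI1, PTCH1, SPRY4, TBR1 and EOMES whatever their result. Some genes that the rule took are not reported here and are left out of the tallies of named genes. Which of the list members allowed by the rule are named as examples was decided after their values were seen.

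The tests, libraries, covariates, lists, naming rule and most alternatives were chosen before the data were examined. These alternatives were RLE size factors, upper-quartile normalization, DESeq2, limma-voom, no low-count filter, a filter at 1 CPM, a minimum of 2-fold, a fit of all 11 libraries, a replicate block, leaving out each library in turn, leaving out mitochondrial, ribosomal, histone and small RNA genes, and both other list tests. Offsets for the GC content of genes in each library (a spline with 6 degrees of freedom over 40 bins), the same with the replicate block, and leaving out both libraries with the lowest GC were added after seeing the data.

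The procedure was tested on simulated counts with the real means and library sizes and a seeded set of changed genes. For PFC against OCC (21174 genes) it called 3.0%, 18.5% and 84.6% of genes changed 1.5, 2 and 4-fold. For OCC against NSC (21825 genes) it called 0.0%, 1.6% and 35.5%, and for PFC against NSC (21645 genes) 0.0%, 3.0% and 59.4%. Unchanged genes made up 6.8%, 4.2% and 7.0% of the calls in that order, 0 calls had the wrong sign, the raised list was called in each comparison, and 0 of 30 unchanged lists were called by camera. Genes were simulated independently of each other, so this could not show false list calls that come from correlated members. The seeded genes were far fewer than the genes called in the real data, which makes the adjustment stricter. These shares therefore do not measure the power of the real comparisons, and small changes could still pass unseen. Figures were drawn with matplotlib 3.10.9.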

Results

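Transcript levels were measured by RNA sequencing in 11 libraries of neural cells derived from human embryonic stem cells. The 4 PFC libraries are d40 cells treated with FGF8 and SHH, secreted signals that pattern the front and the ventral side of the forebrain, and are labelled prefrontal. The 4 OCC libraries are d40 cells maintained from the same kind of neural stem cell and labelled occipital, and the 3 NSC libraries are neural stem cells of the d20 stage. The OCC libraries held 29721979, 28641509, 35711085 and 26647397 counts (replicates 1 to 4). The PFC libraries held 23611599, 24077407, 40773916 and 27925928 counts, and the NSC libraries 32807319, 39509407 and 39902042. The labels name the line H9 for the d40 libraries and MEL1 for NSC, and 8 of the 11 libraries did not match their labelled line in a check of transcripts known to differ between those lines. Protein-coding genes took 89.6 to 92.7% of counts and mitochondrially encoded mRNAs 2.33 to 3.96%. The mean GC content of counts was 47.83% in OCC 2 and 47.57% in PFC 1, against 48.36 to 49.82% in the other libraries.

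The comparison of PFC with OCC asks how cells given FGF8 and SHH, labelled prefrontal, differ from cells labelled occipital. ZIC1 and ZIC4, transcription factor genes that act in the dorsal neural tube and its derivatives, were nearly absent from OCC and abundant in PFC. ZIC1 was at 0.307 ± 0.163 CPM in OCC and 551 ± 95.7 CPM in PFC (SD, n = 4 each). FGF19, which encodes a secreted growth factor, was at 0.0437 ± 0.068 and 73.4 ± 60.6 CPM. In the opposite direction, SST, the gene of the inhibitory neuropeptide somatostatin, was at 258 ± 118 CPM in OCC and 0.411 ± 0.104 CPM in PFC. NR2F1 and NR2F2, nuclear receptor genes active in caudal and ventral parts of the cortex, were at 258 ± 44.7 and 191 ± 36.5 CPM in OCC and 1.35 ± 1.2 and 1.53 ± 0.656 CPM in PFC. FGFR3, a receptor gene with high caudal expression in the cortex, was at 78.9 ± 29.4 and 0.603 ± 0.292 CPM. In total 4229 genes changed (edgeR quasi-likelihood test, adjusted p under 0.05), 2324 higher and 1905 lower in PFC.

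**Figure D1:**
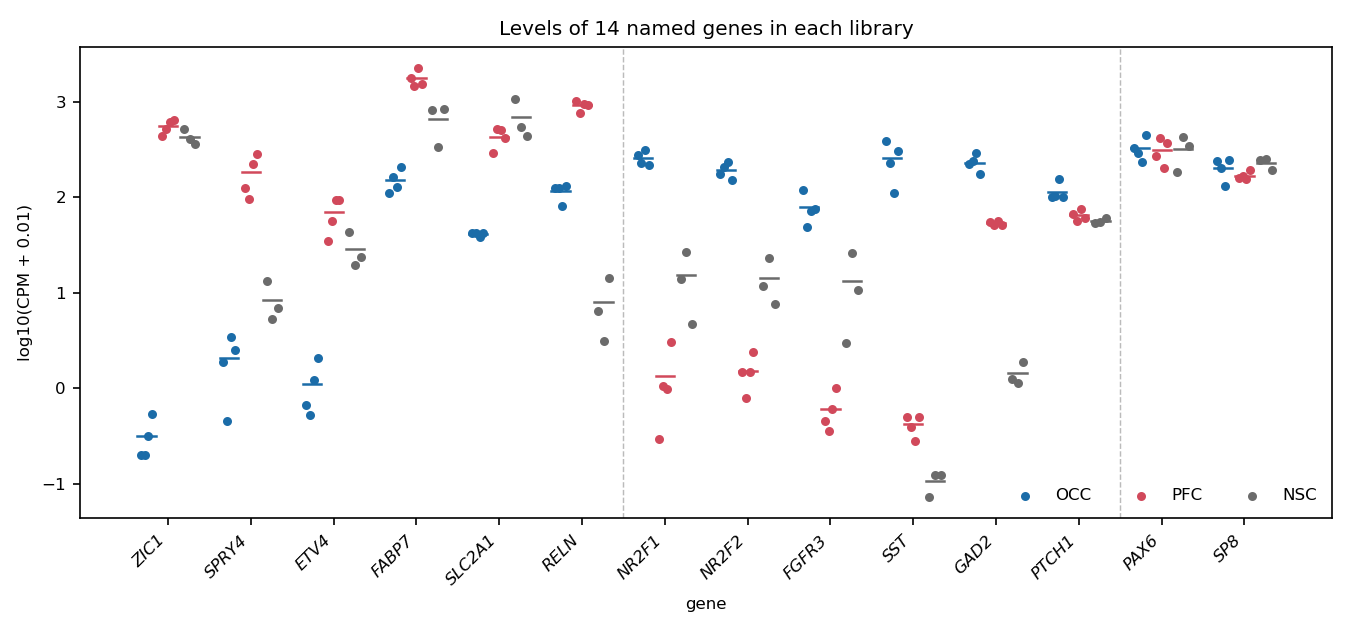
Levels of 14 named genes in each library, as log10 of CPM plus 0.01 on the vertical axis, with each point a library, each short bar the mean CPM of the group, and colours for OCC, PFC and NSC. The first 6 genes were higher in PFC than in OCC, the next 6 were lower, and PAX6 and SP8 did not pass the test; the 4 PFC libraries of ZIC1 lie far above the 4 OCC libraries.

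Among the 12 largest rises in PFC, given as log2 fold change, were ZIC1 (10.79, SE 0.31), FGF19 (10.68, SE 0.90) and ZIC4 (10.25, SE 0.29). Others were NPY2R (7.72, SE 0.73), SLC18A1 (7.45, SE 0.96), DCT (7.39, SE 0.45) and FGF3 (7.31, SE 0.84), and then PRRX1 (7.05, SE 0.42), TFPI (6.73, SE 0.42), TNFSF10 (6.56, SE 0.80) and SPRY4 (6.41, SE 0.59). NPY2R encodes a receptor of neuropeptide Y, SLC18A1 a vesicular monoamine transporter, DCT an enzyme of melanin synthesis, PRRX1 a homeobox factor of mesenchyme and TFPI an inhibitor of blood coagulation. SLC18A1 had 3 counts in the OCC libraries together, which gives a ratio of 220.0 with a 95% counting interval of 74.9 to 1069. Of the 12 largest falls, the first were SST (-9.35, SE 0.50), NR2F1 (-7.6, SE 0.56), FGFR3 (-7.05, SE 0.42) and NR2F2 (-6.99, SE 0.33). They were followed by FGFR2 (-6.3, SE 0.35), PENK (-5.71, SE 0.53), C1QL2 (-5.46, SE 0.75) and ADRA2A (-5.33, SE 0.41). The others were CYP26B1 (-5.19, SE 0.47), CALCR (-4.95, SE 0.78), PDPN (-4.73, SE 0.33) and CACNA2D3 (-4.57, SE 0.45). PENK encodes the enkephalin precursor, ADRA2A an adrenergic receptor, CYP26B1 an enzyme that degrades retinoic acid, CALCR the calcitonin receptor and CACNA2D3 a calcium channel subunit. Adjusted p-values of these genes ran from 4.3e-08 to 0.0018 (edgeR), and in each the 4 PFC libraries lay outside the range of the 4 OCC libraries. The rule for named genes required both passing the threshold and no overlap, so neither is a separate result. On GRCh38, ZIC1 is ENSG00000152977, chromosome 3, 147393422 to 147510293, FGF19 is ENSG00000162344, chromosome 11, 69698232 to 69704642, and SPRY4 is ENSG00000187678, chromosome 5, 142310427 to 142326455. SST is ENSG00000157005, chromosome 3, 187668906 to 187670399, NR2F1 is ENSG00000175745, chromosome 5, 93583224 to 93594615 and FGFR3 is ENSG00000068078, chromosome 4, 1793293 to 1808872.

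Genes of the FGF response were higher in PFC, with 13 of 15 members higher and 1 lower (13 and 1 adjusted over the list alone; median log2 fold change 2.85). Besides SPRY4, SPRY1, another feedback inhibitor of FGF signalling, rose by 5.2 (SE 0.35), and the ETS factor genes ETV1 and ETV4 by 3.75 (SE 0.27) and 5.94 (SE 0.49) on the log2 scale. Camera called this list with adjusted p = 5.4e-23, and adjusted p = 0.14 with an estimated correlation. Caudal and occipital cortex genes were lower in PFC as a list, 5 of 17 members higher and 10 lower both over all genes and adjusted over the list alone (camera, adjusted p = 4.7e-04; adjusted p = 0.17 with an estimated correlation). NR2F1, NR2F2 and FGFR3 were among the falls, while the axon guidance ligand gene EFNA5 rose (3.16, SE 0.24). Genes of the rostral patterning centre and frontal cortex were also lower as a list, 3 of 14 members higher and 5 lower (3 and 7 adjusted over the list alone). Camera gave adjusted p = 0.0056, and adjusted p = 0.14 with an estimated correlation. Within it FGF3 rose, PENK fell, and so did SIX3, a forebrain homeobox gene (-2.65, SE 0.19), and NR2E1, a nuclear receptor gene of neural stem cells (-1.91, SE 0.23). SP8, a rostral factor, did not pass the test (log2 fold change -0.30, adjusted p = 0.31). For cortical hem and choroid plexus the count was 1 of 14 members higher and 2 lower, the same adjusted over the list alone, with OTX2, a homeobox gene, higher (3.06, SE 0.21) and the signal gene BMP6 lower (-3.72, SE 0.44). The list was not called (adjusted p = 0.58), and its median was 0.01, its mean -0.12 and its test direction up.

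PTCH1 and GLI1, genes that hedgehog signalling induces, were lower in the SHH-treated group. PTCH1, the hedgehog receptor gene, was at 114 ± 27 CPM in OCC and 64.7 ± 8.62 CPM in PFC (-0.84, SE 0.17, adjusted p = 0.008, edgeR), with OCC 3 at 155 CPM apart from the other OCC libraries. SHH, the gene of the ligand, had a log2 fold change of -2.85 (SE 0.61), with 205 counts over the OCC and 28 over the PFC libraries. GLI1, an effector and target of the pathway, was at 2.7 ± 2.55 and 0.341 ± 0.398 CPM (-2.94, SE 0.84, adjusted p = 0.034). Its call ended without OCC 3 (adjusted p = 0.056), OCC 4 (0.1), PFC 1 (0.051), PFC 2 (0.092) or PFC 3 (0.084), with a range over its alternatives of 0.001 to 0.1. CDON, a coreceptor gene that the pathway represses, rose by 1.85 (SE 0.16). Over the list the count was 3 of 11 members higher and 4 lower (4 and 5 adjusted over the list alone). Camera did not call it (adjusted p = 0.85), with a median of -0.11, a mean of -0.36 and an upward test direction. SHH is ENSG00000164690, chromosome 7, 155799986 to 155812273, and PTCH1 is ENSG00000185920, chromosome 9, 95442980 to 95517057.

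Ventral telencephalon and interneuron genes were lower in PFC, with 0 of 19 members higher and 11 lower (1 and 12 adjusted over the list alone; camera, adjusted p = 3.5e-09). The list had adjusted p = 0.14 with an estimated correlation. GAD2, an enzyme gene of GABA synthesis, fell from 229.6 ± 47.4 to 53.2 ± 2.41 CPM and SP9, an interneuron factor gene, had a log2 fold change of -2.21 (SE 0.32). NKX2-1, a factor of the medial ganglionic eminence and hypothalamus, fell by 4.01 (SE 0.87) from 2.47 ± 2.69 CPM. Its level was 6.49 CPM in OCC 3 and 0.919 to 1.5 CPM in the other OCC libraries. NKX2-1 is ENSG00000136352, chromosome 14, 36516392 to 36521149. Pan-neuronal genes had 2 of 20 members higher and 10 lower (2 and 11 adjusted over the list alone), with the neuronal factor gene MYT1L (-1.13, SE 0.19) and the vesicle protein gene NSG2 (-1.01, SE 0.12) lower and the neurofilament gene NEFL (2.56, SE 0.32) higher. Camera called the list down with adjusted p = 0.025, and adjusted p = 0.52 with an estimated correlation. This call ended without OCC 3 (0.088) or PFC 4 (0.06), with adjusted p of 0.0073 to 0.52 over its alternatives. The call of NSG2 ended in a fit of all 11 libraries (log2 fold change -0.99, adjusted p = 0.12; range over alternatives 5.8e-13 to 0.12). Glutamate and GABA receptor genes had 4 of 25 members higher and 10 lower (6 and 11 adjusted over the list alone); GRIK3 fell by 3.21 (SE 0.29) and GRIA4 rose by 1.24 (SE 0.16). That list was called down with adjusted p = 0.033, and adjusted p = 0.58 with an estimated correlation. Its call ended without OCC 2 (0.097), PFC 2 (0.065) or PFC 3 (0.15), without both low-GC libraries (0.093) and under fry (0.063), with 0.0042 to 0.58 over all its alternatives.

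Among cortical neuron genes, RELN, the secreted protein of Cajal-Retzius cells, rose from 115 ± 23.6 to 912 ± 105 CPM and BCL11B, a factor of subcerebral neurons, fell from 234 ± 45.5 to 27.5 ± 7.27 CPM. Deep-layer genes had 6 of 17 members higher and 3 lower (6 and 4 adjusted over the list alone). Upper-layer genes had 2 of 13 members higher and 4 lower, the same adjusted over the list alone. Neither list was called (adjusted p = 0.13 and 0.37). TBR1, a cortical projection neuron factor, and EOMES, the factor of intermediate progenitors, had log2 fold changes of 0.84 (SE 0.50) and -0.81 (SE 0.95) and did not pass the test (adjusted p = 0.27 and 0.59). EOMES was at 21.3 CPM in OCC 4 and 0.951 to 1.68 CPM in the other OCC libraries. Without OCC 4 the log2 fold change of EOMES was 1.44 and that of TBR1 was 1.49, the second then past the threshold (adjusted p = 0.046).

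Radial glia and neural stem cell genes had 6 of 21 members higher and 2 lower, the same adjusted over the list alone, and were not called (adjusted p = 0.059). In this list FABP7, a brain lipid-binding protein, rose by 3.51 (SE 0.21), PTPRZ1, a receptor phosphatase, by 1.45 (SE 0.18), and VIM, vimentin, by 1.41 (SE 0.18). PAX6 and SOX2, progenitor factors, had log2 fold changes of -0.06 (SE 0.25) and -0.08 (SE 0.14) and did not pass the test (adjusted p = 0.88 and 0.74). Astrocyte and oligodendrocyte lineage genes were higher as a list, 4 of 13 members higher and 1 lower (5 and 1 adjusted over the list alone). S100B, a calcium-binding protein of astrocytes, was at 0.629 ± 0.131 and 15.3 ± 6.64 CPM, and the glycolytic enzyme gene ALDOC was higher by 2.71 (SE 0.43). The list had adjusted p = 0.0081 (camera; adjusted p = 0.38 with an estimated correlation). Genes of retina and pigment epithelium were higher, 3 of 6 members higher and 0 lower, the same adjusted over the list alone (adjusted p = 1.5e-06; adjusted p = 0.089 with an estimated correlation). DCT, the photoreceptor factor CRX and the visual cycle enzyme RPE65 were those that rose. Only 6 of the 14 listed genes passed the filter, CRX through its PFC counts alone, so most of the list was not tested. CRX rose from 2 counts over the OCC libraries by a ratio of 124 (95% counting interval 33.9 to 1029) and RPE65 by 3.56 (SE 0.42).

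Neural crest and mesenchyme genes had 5 of 13 members higher and 0 lower, the same adjusted over the list alone, among them PRRX1 and COL1A1, a collagen of connective tissue, at 0.251 ± 0.119 and 4.29 ± 2.94 CPM. The list had adjusted p = 4.7e-04, and adjusted p = 0.27 with an estimated correlation. Surface ectoderm and epithelium genes had 4 of 6 members higher and 1 lower (4 and 2 adjusted over the list alone), with the keratin gene KRT8 (4.21, SE 0.49) and the tight junction gene CLDN6 (3.66, SE 0.46) higher. EPCAM, an epithelial adhesion gene, was lower (-1.49, SE 0.34). Camera gave adjusted p = 0.028, and adjusted p = 0.46 with an estimated correlation; the call ended without OCC 3 (0.13), PFC 2 (0.091), PFC 3 (0.12) or PFC 4 (0.17), over a range of 6.3e-04 to 0.46. Genes of pluripotent cells were 4 of 6 members higher and 0 lower, the same adjusted over the list alone, including DPPA4 (2.88, SE 0.36) and the DNA methyltransferase gene DNMT3B (1.11, SE 0.16). This call (adjusted p = 0.0081; adjusted p = 0.25 with an estimated correlation) ended when both low-GC libraries were left out (0.058), over a range of 0.0031 to 0.25.

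Genes of hypoxia and glycolysis were higher in PFC, 14 of 20 members higher and 0 lower (16 and 0 adjusted over the list alone). So were genes of the unfolded protein response, 7 of 16 members higher and 0 lower (8 and 0 adjusted over the list alone). SLC2A1, a glucose transporter, went from 41.3 ± 1.99 to 430.5 ± 106 CPM, and LDHA, lactate dehydrogenase, from 95.4 ± 45.1 to 554 ± 126 CPM. PFKFB4, a regulator of glycolysis, rose by 2.23 (SE 0.26), a call that ended in a fit of all 11 libraries (log2 fold change 2.27, adjusted p = 0.059; range over alternatives 1.4e-15 to 0.059). The chaperone gene HSPA5 rose by 0.84 (SE 0.13) and XBP1, a factor of the unfolded protein response, by 1.2 (SE 0.19). Camera gave adjusted p = 1.4e-13 for hypoxia and 0.0021 for the unfolded protein response, against adjusted p = 0.17 and adjusted p = 0.27 with an estimated correlation. Cell division genes were called down with 0 of 25 members higher and 2 lower (0 and 1 adjusted over the list alone), among them MCM4, a replication helicase subunit, which fell by 0.92 (SE 0.20). Its list had adjusted p = 0.0059, and adjusted p = 0.73 with an estimated correlation, and the call ended under fry (0.17) and without PFC 2 (0.091), over a range of 9.7e-05 to 0.73.

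Of the lists that camera did not call, retinoic acid response genes had 3 of 12 members higher and 5 lower (3 and 6 adjusted over the list alone). In it CYP26B1 and the homeobox gene MEIS1 (-1.45, SE 0.24) were lower and the retinol dehydrogenase gene RDH10 was higher (1.86, SE 0.31). Notch pathway genes had 0 of 14 members higher and 4 lower, the same adjusted over the list alone, among them the ligand gene JAG1, which fell by 1.57 (SE 0.15). Synapse and axon adhesion genes had 5 of 30 members higher and 8 lower (5 and 9 adjusted over the list alone). NLGN1, a postsynaptic adhesion gene, and ROBO1, an axon guidance receptor gene, rose by 1.8 (SE 0.25) and 1.02 (SE 0.10). Autism-associated genes had 7 of 44 members higher and 10 lower (9 and 13 adjusted over the list alone), including the glutamate receptor gene GRIN2B, which fell by 1.92 (SE 0.35). WNT genes had 4 of 13 members higher and 0 lower (5 and 1 adjusted over the list alone), BMP genes 1 of 12 members higher and 2 lower (3 and 3), and hypothalamus genes 0 of 7 members higher and 3 lower (1 and 3). Intermediate progenitor genes had 0 of 13 members higher and 2 lower (0 and 2 by the same adjustment), mitochondrially encoded mRNAs 0 of 13 members higher and 1 lower (0 and 1), histones 0 of 37 members higher and 4 lower (0 and 3) and cytosolic ribosomal proteins 3 of 73 members higher and 0 lower (0 and 0). Adjusted p-values of these 11 lists lay between 0.058 and 0.99. Too few members passed the filter for a list test of thalamus and other diencephalon (2 of 4 members higher and 0 lower), midbrain and hindbrain (2 of 4 members higher and 2 lower), endoderm and mesoderm (0 of 3 members higher and 0 lower) and small RNAs (0 of 4 members higher and 0 lower). In addition, 0 of 39 HOX genes, markers of hindbrain and spinal cord, had enough counts to be tested. Camera called 14 of the 30 tested lists; with an estimated correlation it called 0, with 6 at unadjusted p under 0.05, and fry called 12.

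**Figure D2:**
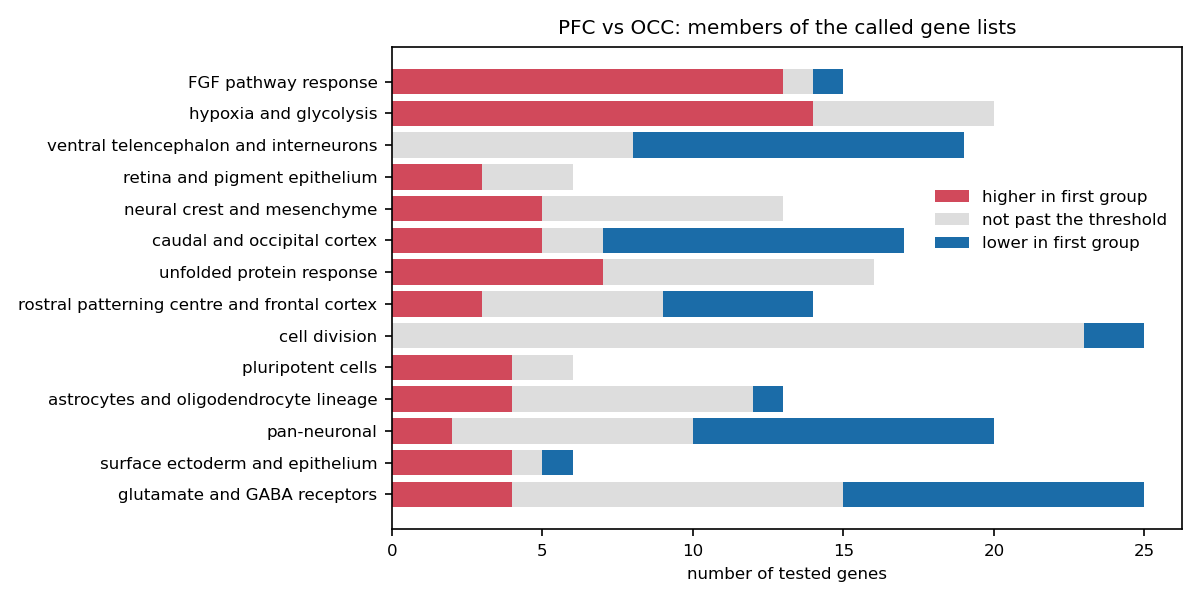
Number of tested genes (horizontal axis) in each of the 14 gene lists that camera called between PFC and OCC, with bars divided into members higher in PFC (red), not past the edgeR threshold (grey) and lower in PFC (blue). The FGF response list has 13 of 15 members higher, and the ventral telencephalon list 11 of 19 lower.

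Comparing OCC with NSC shows how the d40 cells labelled occipital differ from the neural stem cell stage, with the limit that labelled line, RNA selection and series change with stage. Some neuronal genes were far higher in OCC. GAD2 was at 1.43 ± 0.409 CPM in NSC (SD, n = 3) and 229.6 ± 47.4 CPM in OCC (n = 4). MYT1L was at 0.70 ± 0.369 and 169 ± 21.1 CPM, and GRIK3 at 1.48 ± 1.03 and 693 ± 23.7 CPM. NSC held transcripts nearly absent from OCC, such as the desmosome gene DSP (269 ± 35.5 against 0.303 ± 0.227 CPM) and ZIC1 (426 ± 81.7 against 0.307 ± 0.163 CPM). In all 11161 genes changed (edgeR, adjusted p under 0.05), 5682 higher and 5479 lower in OCC, a balance that turned with RLE size factors (5528 and 5687), among other settings. The 6 largest rises were GPR26, SST, ZNF804B, KLHL1, C6 and GPR12. GPR26 and GPR12 encode G protein-coupled receptors, KLHL1 a neuronal kelch protein and C6 a complement component. SST rose by 11.35 (SE 0.64) on the log2 scale. GPR26, KLHL1, ZNF804B and C6 had 0 counts in NSC and were at least 900.0, 208, 226 and 151-fold higher in OCC. GPR12 had 2 counts in NSC, a ratio of 1066 (95% counting interval 295 to 8806). The 6 largest falls were CAVIN3, ZIC1 (-10.40, SE 0.38), ZIC4 (-9.75, SE 0.53), DSP (-9.74, SE 0.50), the keratin gene KRT19 (-9.44, SE 0.59) and the annexin gene ANXA3 (-9.35, SE 1.23). CAVIN3, a caveola gene, had 0 counts in OCC and was at least 248-fold higher in NSC. DSP is ENSG00000096696, chromosome 6, 7541575 to 7586717, GAD2 is ENSG00000136750, chromosome 10, 26216307 to 26304558, and MYT1L is ENSG00000186487, chromosome 2, 1789113 to 2331664 on GRCh38.

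Pan-neuronal genes rose in OCC, 18 of 20 members higher and 0 lower, the same adjusted over the list alone, among them the synaptic vesicle fusion gene SNAP25 (5.21, SE 0.27) and MYT1L (7.95, SE 0.41). Glutamate and GABA receptor genes had 22 of 25 members higher and 1 lower and ventral telencephalon and interneuron genes 17 of 19 members higher and 0 lower, both the same adjusted over the list alone. Synapse and axon adhesion genes had 19 of 30 members higher and 3 lower (20 and 3 adjusted over the list alone). GRIK3 rose by 8.92 (SE 0.56), GAD2 by 7.37 (SE 0.32), the interneuron homeobox gene DLX6 by 9.59 (SE 0.51) and the adhesion gene CNTN1 by 6.46 (SE 0.45). Autism-associated genes had 22 of 44 members higher and 7 lower, the same adjusted over the list alone, with GRIN2B (7.22, SE 0.64) and the sodium channel gene SCN2A (6.25, SE 0.47) higher. Adjusted p-values by camera were 1.5e-18 for pan-neuronal, 2.9e-15 for receptors, 1.8e-16 for ventral, 3.5e-07 for synapse and 4.9e-04 for autism-associated genes. In the same order they were adjusted p = 0.1, 0.1, 0.1, 0.11 and 0.23 with an estimated correlation. NKX2-1 rose from 1 count over the NSC libraries by a ratio of 310.0 (95% counting interval 55.2 to 12263), with OCC 3 at 6.49 CPM against 0.919 to 1.5 CPM in the other OCC libraries.

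Lower in OCC were all tested cell division genes, 0 of 25 members higher and 25 lower, such as the replication genes MCM3 (-2.62, SE 0.27) and TYMS (-2.64, SE 0.25). So were most cytosolic ribosomal protein genes, 0 of 73 members higher and 68 lower (0 and 70 adjusted over the list alone), such as RPL41 (-1.8, SE 0.18). Camera gave adjusted p = 4.4e-14 and 2.0e-16, against adjusted p = 0.23 and adjusted p = 0.3 with an estimated correlation. FGF response genes had 2 of 16 members higher and 13 lower, the same adjusted over the list alone, with SPRY1 (-5.21, SE 0.45) and IL17RD, an inhibitor of FGF signalling (-3.23, SE 0.17), lower. Camera gave adjusted p = 5.8e-06, and adjusted p = 0.23 with an estimated correlation. SPRY4 fell by 1.98 (SE 0.59, adjusted p = 0.021), a call that ended without OCC 1 (0.059) or NSC 1 (0.053), over a range of 0.002 to 0.059. The log2 fold changes of SPRY4 were then -1.92 and -1.50. Cortical hem and choroid plexus genes had 0 of 17 members higher and 12 lower (0 and 13 adjusted over the list alone), including OTX2 (-4.16, SE 0.24) and BMP7 (-4.81, SE 0.66). WNT response genes had 1 of 13 members higher and 10 lower (2 and 10 adjusted over the list alone), including the receptor gene LGR5 (-5.92, SE 0.57). Their adjusted p-values were 3.3e-05 and 0.0055, against adjusted p = 0.3 and adjusted p = 0.31 with an estimated correlation. Radial glia genes had 2 of 21 members higher and 8 lower, the same adjusted over the list alone, with PROM1, an apical membrane gene (-3.42, SE 0.32), and SOX2 (-1.26, SE 0.18) lower. This list had adjusted p = 0.029, and adjusted p = 0.31 with an estimated correlation, and its call ended without OCC 2 (0.054), over a range of 0.0056 to 0.31.

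Surface ectoderm and epithelium genes had 2 of 9 members higher and 6 lower, KRT8 among the falls (-9.08, SE 0.37), and neural crest and mesenchyme genes 0 of 14 members higher and 10 lower, COL1A1 among them (-7.0, SE 0.77, and -5.80 without NSC 1). Pluripotent cell genes had 1 of 7 members higher and 5 lower, LIN28A, an RNA-binding regulator of early cells, among them (-5.92, SE 0.57). Each count was the same adjusted over the list alone. The camera test gave adjusted p = 3.3e-05, 0.0017 and 0.0029, and in that order adjusted p = 0.21, 0.11 and 0.11 with an estimated correlation. Hypoxia and glycolysis genes had 0 of 20 members higher and 8 lower (0 and 7 adjusted over the list alone), with SLC2A1 (-4.02, SE 0.31) and LDHA (-2.73, SE 0.65) lower in OCC. The list's call (adjusted p = 0.036; adjusted p = 0.66 with an estimated correlation) ended under fry (0.19) and without OCC 3 (0.058), OCC 4 (0.064) or NSC 1 (0.39), over a range of 9.9e-04 to 0.66. LDHA was at 1422 CPM in NSC 1 and 256 and 259.6 CPM in NSC 2 and NSC 3, and without NSC 1 its log2 fold change was -1.39 (adjusted p = 0.012).

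Cortical regional genes moved both ways between OCC and NSC. Rostral genes had 7 of 14 members higher and 4 lower and caudal genes 7 of 17 members higher and 8 lower, both the same adjusted over the list alone. Neither list was called (adjusted p = 0.12 and 0.57), the caudal list with a median of -0.51 and a mean of 0.12. NR2F1 rose by 4.12 (SE 0.55), and NPY, the gene of neuropeptide Y, from 2 counts in NSC by a ratio of 755 (95% counting interval 209 to 6242). CYP26B1 rose by 5.39 (SE 0.52). BCL11B rose by 8.56 (SE 0.60), and the deep-layer list, with 6 of 18 members higher and 3 lower, was not called (adjusted p = 0.15). PTCH1 rose by 1.06 (SE 0.21), and the hedgehog list, with 4 of 11 members higher and 6 lower, was not called either (adjusted p = 0.14). Both counts were the same adjusted over the list alone. PAX6 (0.07), SP8 (-0.13), GLI1 (0.30), TBR1 (0.42) and EOMES (-2.62) did not pass. EOMES did so without OCC 4 (log2 fold change -4.93, adjusted p = 7.7e-04), with limma-voom (-3.72, 0.0091), without a low-count filter (-2.68, 0.023) and in a fit of all 11 libraries (-2.67, 0.037). In total camera called 15 of 33 tested lists; with an estimated correlation it called 0, with 7 at unadjusted p under 0.05, and fry called 26.

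PFC and NSC differ in the same confounded ways, and their comparison asks how the FGF8 and SHH treated d40 cells differ from the neural stem cell stage. Some interneuron genes were far higher in PFC. DLX1, a homeobox gene of interneuron progenitors, was at 0.666 ± 0.582 CPM in NSC (n = 3) and 160.0 ± 36.5 CPM in PFC (n = 4), and DLX2 at 0.802 ± 0.289 and 66 ± 5.82 CPM. RELN was at 8.03 ± 5.8 and 912 ± 105 CPM, and GRIA2, an AMPA receptor subunit gene, at 2.37 ± 1.98 and 672 ± 378 CPM. NOS2, inducible nitric oxide synthase, was at 234 ± 157 CPM in NSC and 1.9 ± 0.446 CPM in PFC. A total of 8486 genes changed (edgeR, adjusted p under 0.05), 4091 higher and 4395 lower in PFC; without NSC 2 the number was 5489. The balance of directions turned with upper-quartile scaling (4738 higher and 3670 lower), among other settings. The 6 largest rises were KLHL1, GPR26, TLE2, TAC1, the precursor gene of substance P (10.27, SE 0.68), DLX6 (8.75, SE 0.60) and the extracellular matrix gene TNR (8.43, SE 0.54). KLHL1 and GPR26 had 0 counts in NSC and were at least 287 and 184-fold higher in PFC. TLE2, a corepressor gene, had 2 counts in NSC, a ratio of 702 (95% counting interval 194 to 5801). The 6 largest falls were NRAP, HPSE2 (-7.32, SE 0.64), the signal gene WNT8B (-7.12, SE 1.08), NOS2 (-6.92, SE 0.48), ID3, a BMP target (-6.9, SE 0.94), and CDC20B (-6.69, SE 0.64). NRAP had 3 counts in PFC, a ratio of 194 in favour of NSC (interval 66.1 to 945). Without NSC 2 the log2 fold changes of WNT8B and ID3 were -4.66 and -5.68. DLX1 is ENSG00000144355, chromosome 2, 172084740 to 172089677, RELN is ENSG00000189056, chromosome 7, 103471784 to 103989516, and NOS2 is ENSG00000007171, chromosome 17, 27756766 to 27800499.

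Each of the 20 pan-neuronal genes rose in PFC (20 of 20 members higher and 0 lower; the same adjusted over the list alone), with MYT1L higher by 6.83 (SE 0.46) and SNAP25 by 4.49 (SE 0.30). Ventral telencephalon and interneuron genes had 13 of 17 members higher and 0 lower (14 and 0 adjusted over the list alone), including GAD2 (5.24, SE 0.27). Both lists were called with the preset correlation (adjusted p = 1.1e-25 and 5.6e-15) and also passed with adjusted p = 0.033 and adjusted p = 0.033 with an estimated correlation. Receptor genes had 21 of 25 members higher and 0 lower, the same adjusted over the list alone, with GRIA2 higher by 8.18 (SE 0.82). Synapse genes had 18 of 30 members higher and 1 lower (19 and 1 adjusted over the list alone), with CNTN1 higher by 6.54 (SE 0.44). Autism-associated genes had 16 of 44 members higher and 4 lower (17 and 5 adjusted over the list alone), with SCN2A higher by 6.17 (SE 0.43). The camera test gave adjusted p = 2.9e-17, 1.4e-10 and 4.7e-05, and in that order adjusted p = 0.12, 0.15 and 0.15 with an estimated correlation. Deep-layer genes had 8 of 17 members higher and 3 lower (9 and 3 adjusted over the list alone), with RELN (6.86, SE 0.54) and BCL11B (5.45, SE 0.61) higher and the subcerebral neuron factor FEZF2 lower (-2.46, SE 0.38). Their call by camera (adjusted p = 0.02, and adjusted p = 0.41 with an estimated correlation) ended without NSC 1 (0.085), over a range of 0.003 to 0.41. The list includes RELN, described above as a gene of Cajal-Retzius cells, and its member TBR1 did not pass. Its call therefore does not show a rise specific to deep-layer neurons.

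Lower in PFC than in NSC were all tested cell division genes, 0 of 25 members higher and 25 lower, with MCM3 (-3.03, SE 0.34) and TYMS (-2.58, SE 0.29). So were 65 of 73 ribosomal protein genes (69 adjusted over the list alone), with RPL41 (-1.55, SE 0.15). Their adjusted p-values were 2.1e-17 and 2.9e-20, against adjusted p = 0.24 and adjusted p = 0.24 with an estimated correlation. Caudal cortex genes had 3 of 17 members higher and 10 lower, the same adjusted over the list alone, among them NR2F1 (-3.48, SE 0.76), EMX2, a dorsal cortex factor (-2.06, SE 0.28), and DMRTA1, a cortical progenitor factor (-4.53, SE 0.30). Cortical hem and choroid plexus genes had 0 of 16 members higher and 13 lower, the same adjusted over the list alone, among them WNT2B (-2.97, SE 0.34) and the WNT agonist gene RSPO1 (-4.54, SE 0.55). WNT genes had 0 of 13 members higher and 7 lower, with LGR5 lower (-4.14, SE 0.67), and Notch genes 1 of 14 members higher and 6 lower, with JAG1 lower (-4.12, SE 0.19), both the same adjusted over the list alone. BMP genes had 0 of 14 members higher and 5 lower (0 and 6 adjusted over the list alone), with the target gene ID1 lower (-6.14, SE 0.78; -5.02 without NSC 2). For caudal, hem, WNT, Notch and BMP genes camera gave adjusted p = 5.4e-04, 8.9e-07, 0.013, 0.0027 and 0.029. In that order they had adjusted p = 0.24, 0.24, 0.41, 0.37 and 0.41 with an estimated correlation.

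Genes of the hedgehog list were lower in PFC, 1 of 11 members higher and 6 lower, the same adjusted over the list alone, with GLI3, the main repressor of the pathway, at -1.64 (SE 0.19). The list mixes genes that the pathway induces with genes that it represses or that oppose it. Its direction therefore does not measure the response of the pathway. GLI1 fell by 2.68 (SE 0.89, adjusted p = 0.041). The list's call (adjusted p = 0.048; adjusted p = 0.39 with an estimated correlation) ended without PFC 2 (0.075) or NSC 1 (0.058) and with GC-content offsets (0.054), over a range of 0.0095 to 0.39. GLI1, whose ranges overlapped, lost its call without PFC 1 (0.059), PFC 2 (0.098), PFC 3 (0.098), NSC 2 (0.063) or NSC 3 (0.15), over a range of 0.0073 to 0.15. Its log2 fold changes were then -2.28, -2.46, -2.59, -2.84 and -1.96 in that order. PTCH1, the receptor gene, did not pass (log2 fold change 0.22, SE 0.17, adjusted p = 0.34). FGF response genes had 7 of 16 members higher and 3 lower, the same adjusted over the list alone, and the list was not called (adjusted p = 0.051). SPRY4 rose by 4.45 (SE 0.51) and the phosphatase gene DUSP4 by 2.02 (SE 0.25). Hypothalamus genes were called down, 1 of 9 members higher and 5 lower (1 and 7 adjusted over the list alone; adjusted p = 0.0023, and adjusted p = 0.24 with an estimated correlation). So were surface ectoderm genes, 1 of 8 members higher and 6 lower, with KRT8 (-4.86, SE 0.50), and crest and mesenchyme genes, 0 of 13 members higher and 5 lower, both the same adjusted over the list alone. The camera test gave these adjusted p = 0.0019 and 0.027, and in that order adjusted p = 0.27 and 0.27 with an estimated correlation. Hypoxia genes had 1 of 21 members higher and 0 lower (0 and 0 adjusted over the list alone) and were not called (adjusted p = 0.53). Over 20 of them the median centred log2 level was 1.86 in NSC 1, -0.55 and -0.65 in NSC 2 and NSC 3, and 0.46 to 1.2 in the PFC libraries. LIN28A fell by 4.89, and its list of pluripotent cell genes, with 1 of 8 members higher and 2 lower, was not called (adjusted p = 0.11). SOX2 (-1.33, SE 0.15) and EOMES (-3.46, SE 0.62) were lower. PAX6 (0.01), SP8 (-0.42) and TBR1 (1.24) did not pass. TBR1 passed without NSC 3 (log2 fold change 1.80, adjusted p = 0.046) and without a low-count filter (1.19, 0.048), and SP8 with DESeq2 (-0.43, 0.048). Camera called 17 of 34 tested lists; with an estimated correlation it called 2, and fry called 21.

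**Figure D3:**
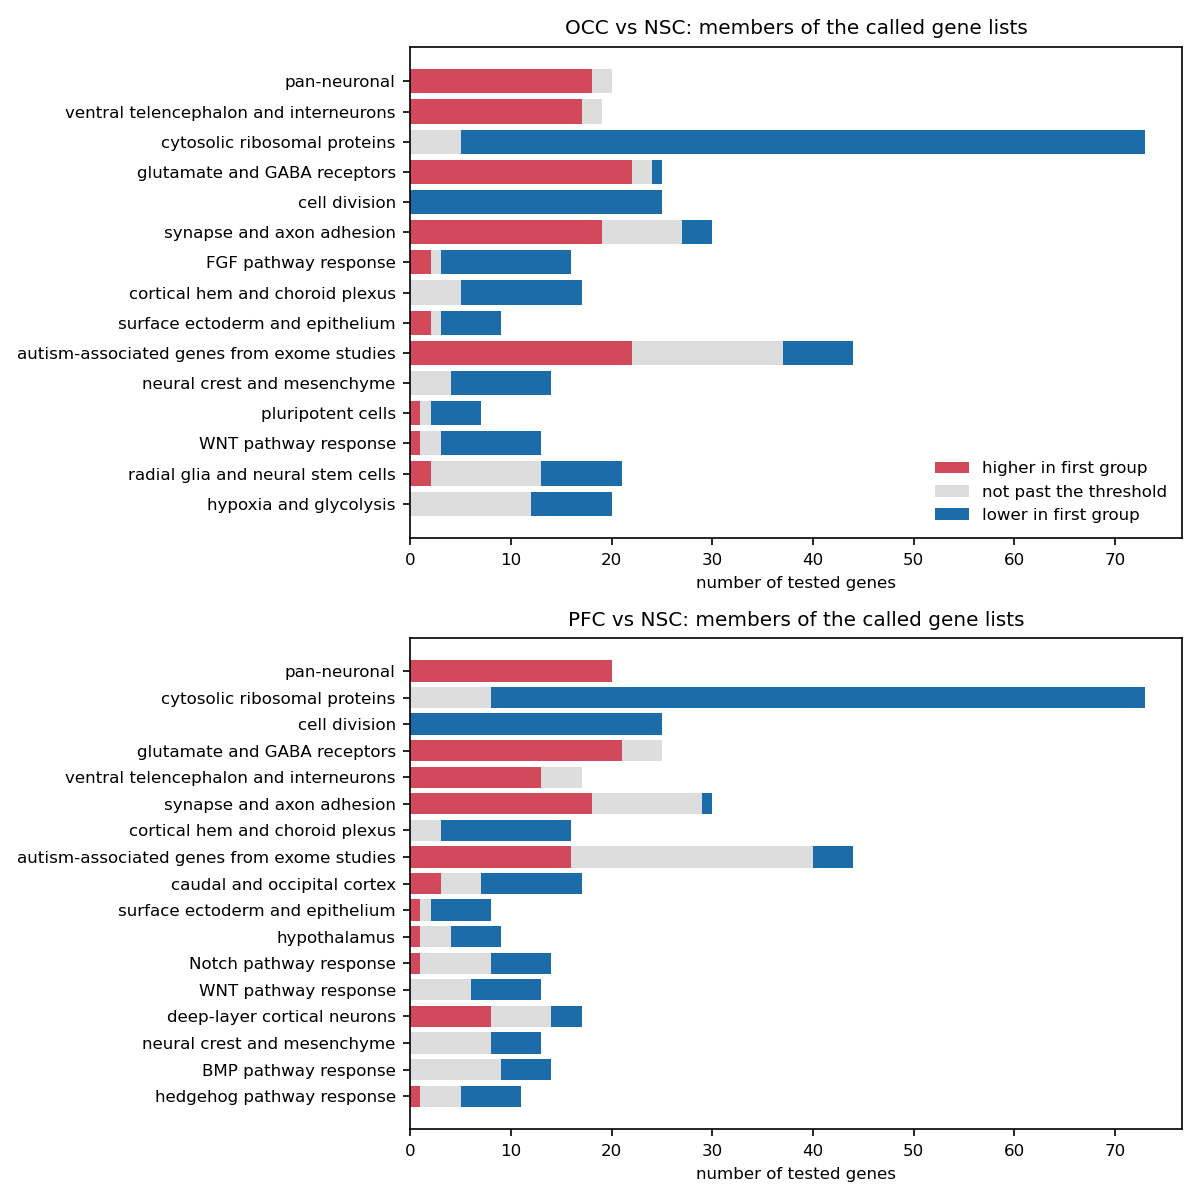
Number of tested genes (horizontal axis) in each gene list that camera called between OCC and NSC (15 lists, upper panel) and between PFC and NSC (17 lists, lower panel). Bars are divided into members higher in the d40 group (red), not past the edgeR threshold (grey) and lower in it (blue); all 25 cell division genes were lower in both panels, and neither panel separates stage from labelled line or RNA selection.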

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

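The comparison of OCC 2 with PFC 1 for shared cells or RNA, the tests of swapped labels and of SHH transcripts, and those of RNA selection and cell line were chosen only after the results were seen. The tests of GC content and of other splits of the libraries were set out before their results were seen.

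OCC 2 and PFC 1 departed from their groups together: the mean GC content of counts was 47.57% in PFC 1 against 48.83 to 49.06% in the other PFC libraries, and the deviations of both libraries from their group means had a correlation of 0.70 over 15288 genes. After the GC trend of each library was removed the correlation was 0.44 (SE 0.02, leaving out 23 chromosomes in turn), so the trend accounts for part. That SE measures spread over genes, not between libraries. By the same measure OCC 3 with PFC 3 had 0.4 and OCC 4 with PFC 4 had 0.32. The pair was noticed for its high correlation, and a spline over gene GC content may leave other GC effects. This test therefore cannot exclude GC bias as the whole cause. Over the 12 largest falls the median ratio of PFC 1 to the mean of the other PFC libraries was 0.831. The rule took these genes partly for low levels in PFC 1 itself, so this ratio cannot exclude OCC cells or RNA in PFC 1. Carry-over of PFC cells or RNA into OCC 2 was not tested. A step of handling shared by these libraries stays open, since no label gives a batch, and no biological explanation was tested. Without both libraries 5625 genes changed between PFC and OCC.

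PTCH1 and GLI1 were lower in the arm treated with SHH. The median log2 fold change of the FGF list, 2.85 in PFC over OCC, argues against swapped arm labels, and PTCH1 kept a fold change of -0.84 (SE 0.15, adjusted p = 0.0024, edgeR) with GC-content offsets, which argues against GC bias. SHH itself had a log2 fold change of -2.85 (adjusted p = 0.0095, edgeR), so more ligand made by the OCC cultures may be a candidate explanation and remains a hypothesis. Whether the factors were still given at harvest, which the labels do not say, and a repressed response in the cells, stay open as untested. The call of GLI1 ended without OCC 3, OCC 4, PFC 1, PFC 2 or PFC 3, with log2 fold changes of -3.08, -2.09, -2.57, -2.71 and -2.86 in that order.

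Between d40 and NSC libraries 11161 (OCC) and 8486 (PFC) genes changed, and if total RNA in the d40 libraries were the source, they would hold more non-polyadenylated RNA. For small RNA only 1 of the 8 d40 libraries had a share above every NSC library (0.0015 to 0.013% of counts against 0.0033 to 0.011%), while for histone mRNA 8 did (0.027 to 0.048% against 0.012 to 0.021%), although cell division genes were lower at d40. Within the histone share, H2BC21 was at 131, 87.1 and 17.9 CPM in OCC, PFC and NSC, and the pseudogene H2BC20P at 67.3, 33.7 and 10.4 CPM. The histone genes themselves went both ways (12 of 42 members higher and 13 lower in OCC over NSC, 8 of 41 members higher and 10 lower in PFC over NSC; camera, adjusted p = 0.76 and 0.91), the classes differ, and RNA selection changes with stage in every library, so that these cannot be told apart. The number of cell lines labelled at both stages was 0, so that line and stage cannot be told apart, and 8 of 11 libraries did not match their labelled line. A biological difference of stage, which the design names, stays open.

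Other splits of the same libraries into groups of the same sizes were tested, 35 per comparison with the real split included. For PFC against OCC 1 split, the real one, called as many genes (4229 against at most 0 in the others by edgeR, 7161 against at most 4188 at unadjusted p under 0.05). For OCC against NSC it was again 1 (11161 against 0, unadjusted 12769 against 5276) and for PFC against NSC 1 (8486 against 1, unadjusted 10843 against 5404). Every other split mixed libraries of both groups, so the group difference entered its residual spread and lowered its calls. The real split was thus the most extreme of the 35, but this test cannot exclude chance for the gene counts. The numbers of called lists did not set the real split apart: 5 of 35 splits called as many for PFC against OCC (14 against up to 20), 9 for OCC against NSC (15 against up to 22) and 6 for PFC against NSC (17 against up to 18). Splits that mixed the groups unequally kept part of the group difference, so this test cannot decide whether the list counts exceed chance.

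Single libraries stood apart from the other 3 of their group in 27 of 248 tests over 117 genes and library measures. Chance gives about 1 in 20 only if values are normally distributed. CPM values were not shown to be so, and some lie near the floor, so these numbers do not show an excess over chance. In OCC 4 the values that stood apart, in CPM with the range of the other OCC libraries, were EMX2 37 (3.36 to 4.39), EOMES 21.3 (0.951 to 1.68), FEZF2 10.3 (0.485 to 1.68), GLI1 6.48 (1.03 to 1.9) and GLI3 208 (105 to 121). The others in OCC 4 were MCM3 89 (57.9 to 61.7), NPY2R 0.215 (0 to 0.0323), RSPO1 3.72 (0.226 to 0.634) and WNT8B 2.94 (0.097 to 0.349). In OCC 3 they were LIN28A 3.94 (1.96 to 2.26), NKX2-1 6.49 (0.919 to 1.5), PTCH1 155 (102 at most), RELN 80.2 (123 to 131), RPE65 0.196 (0.743 to 0.824) and SLC2A1 38.3 (41.9 to 42.5). OCC 2 was highest for GRIN2B at 469 (256 to 291) and SCN2A at 239 (112 to 130.0), and OCC 1 for GRIK3 at 728 (678 to 686). Among PFC libraries, PFC 1 stood apart for CLDN6 at 2.92 (8.07 to 8.71), GRIA2 at 1237 (459 to 531) and WNT2B at 26.7 (17.4 to 18.6). PFC 2 did so for C1QL2 at 0.311 (0.0249 to 0.0411) and XBP1 at 35.8 (26.2 to 27.7), PFC 3 for DPPA4 at 239 (98.5 to 122), and PFC 4 for BMP7 at 22.9 (5.1 to 7.41) and RDH10 at 18.7 (28.3 to 28.8). The same genes entered more than 1 of the lists, and these tests are not independent.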

How the results depend on the processing

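Offsets for GC content, the same with the replicate block, and leaving out both low-GC libraries were chosen only after the data were seen; the other alternatives were set beforehand. Between PFC and OCC 4229 genes changed. Alternatives gave 2693 genes with at least 2-fold change (the threshold is stricter by construction) and 6418 with GC-content offsets and the replicate block (4124 of them among the 4229; the cause was not tested). They gave 5733 with the offsets alone, 5625 without both low-GC libraries and 2926 to 5254 leaving out single libraries. OCC against NSC gave 9021 to 13828 genes leaving out single libraries, and PFC against NSC 5489 to 12049, the lowest without NSC 2 (5357 of the 8486 were shared, and the cause was not tested). In both comparisons the highest number was that without NSC 1. Upper-quartile scaling gave 6330 higher and 4820 lower genes for OCC over NSC and 4738 and 3670 for PFC over NSC, and moved the median log2 fold change of all genes from 0.01 to 0.14 and from 0.00 to 0.13.

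Camera with an estimated correlation called 0, 0 and 2 lists for PFC against OCC, OCC against NSC and PFC against NSC, in place of 14, 15 and 17 (unadjusted p under 0.05: 6, 7 and 6). The estimates lay on both sides of the preset 0.01. Between PFC and OCC the FGF list had 0.524 and the rostral list -0.048. Between OCC and NSC the pluripotent list had -0.127 and the crest and mesenchyme list -0.034. A correlation above the preset thus does not account for the lost calls of the rostral, pluripotent and crest lists. The cause of the other losses was not tested. Fry called 12, 26 and 21 lists; it does not compare a list with other genes. Leaving out single libraries gave 12 to 19, 15 to 21 and 17 to 20 lists.

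The replicate numbers were not taken to pair the samples: the deviations of same-numbered OCC and PFC libraries had correlations of -0.52, -0.17, 0.41 and 0.32 for numbers 1 to 4, and 3 of 8 libraries correlated best with their own number. After each library's GC trend was removed the correlations were -0.04, 0.16, 0.4 and 0.32, and 5 of 8 libraries did so. These correlations hint at pairs except for number 1, where they cannot exclude a pair. Same-numbered OCC and PFC libraries also share the sheet's line number, and the sample codes in their titles are close. The main test may therefore ignore a pairing. With the number as a block, 3344, 7940 and 6531 genes changed and 13, 20 and 19 lists were called in the 3 comparisons, in the order above. In the comparisons with NSC the block has no stated basis, since it joins libraries of different series by title number. It also left out OCC 4 and PFC 4, which have no NSC library of the same number. Under the block surface ectoderm (adjusted p = 0.069) and pan-neuronal (0.13) were not called between PFC and OCC, and TBR1 was (0.018; 0.005 with offsets and block), as was EOMES between OCC and NSC (0.0021).

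Of 154 called gene results, none changed sign under any alternative, 2 log2 fold changes moved over 1.5 times when 1 library was left out (LDHA and WNT8B), and 40 moved over 1.5-fold on the linear scale. Between PFC and OCC the 40 included SHH, DCT, C1QL2, CALCR, FGF19, FGF3, GLI1, NKX2-1, NPY2R, NR2F1, SLC18A1, TFPI and TNFSF10. Between OCC and NSC they included GRIK3, GRIN2B, BCL11B, BMP7, COL1A1, LDHA, GPR12, NKX2-1, NR2F1 and ZIC4. The others, between PFC and NSC, were DLX1, GRIA2, RELN, BCL11B, LGR5, ID1, CDC20B, EOMES, GLI1, HPSE2, ID3, NOS2, NR2F1, NRAP, TAC1, TLE2 and WNT8B. Signs reversed only for genes not past the threshold. Between PFC and OCC these were EOMES (0.27 with limma-voom, 0.18 with the block, -1.41 to 1.44 leaving out single libraries, the highest without OCC 4, 0.15 with offsets and block), PAX6 (-0.22 to 0.10, the highest without OCC 4 and PFC 3), SOX2 (-0.16 to 0.02, the highest without OCC 4) and SP8 (0.03 with offsets and block). Between OCC and NSC they were GLI1 (-0.40 block, -0.59 without OCC 4, -0.10 without NSC 1), PAX6 (-0.05 block, -0.11 without OCC 4, -0.21 without NSC 1, up to 0.29), SP8 (0.07 without OCC 3, as low as -0.26, 0.11 offsets) and TBR1 (-0.14 block, -0.25 without OCC 4, -0.05 without NSC 2, up to 0.97). Between PFC and NSC they were PAX6 (-0.01 with RLE and with DESeq2, -0.03 without a filter, -0.04 block, -0.02 all 11 libraries, -0.14 without PFC 2, -0.07 without PFC 4, -0.28 without NSC 1, up to 0.26) and SP8 (0.02 offsets); the cause of these reversals was not tested. DESeq2 gave no adjusted p for EOMES (PFC against OCC), LDHA (OCC against NSC) and WNT8B (PFC against NSC). Depth limits NKX2-1, SHH and GLI1, which had few counts in at least 1 group.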

Other observations

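The median centred log2 level of the FGF response list was -2.03 to -0.88 in OCC, 0.92 to 1.65 in PFC and 0.20 to 0.68 in NSC libraries. SPRY1 was at 146 ± 52.4 CPM in NSC (n = 3) and 142 ± 24.8 CPM in PFC (n = 4), while SPRY4 was at 8.44 ± 4.15 CPM in NSC and 181 ± 86.3 CPM in PFC. ZIC1 and ZIC4, nearly absent from OCC, were at 426 ± 81.7 and 142 ± 86.5 CPM in NSC.

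The hypoxia and glycolysis list set NSC 1 apart from NSC 2 and NSC 3, with median centred log2 levels of 1.86, -0.55 and -0.65. The titles divide them in the same way, since only NSC 2 and NSC 3 carry the code R6, and the cause was not tested. The OCC libraries lay at -0.57, -0.18, -1.44 and -1.55 and the PFC libraries at 0.90, 1.2, 0.85 and 0.46. Cell division genes were lowest in PFC 2 at -1.72, against -0.69, -0.26 and -0.52 in PFC 1, PFC 3 and PFC 4. Intermediate progenitor genes were highest among the d40 libraries in OCC 4 at 0.82, the library with the highest EOMES level.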
